A study of Mus musculus with 2 samples.

How the data were processed

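Chromatin accessibility was measured by ATAC-seq after Nextera tagmentation in 2 biological replicates of 1 group, E12.5 midbrain. Replicate 1 was a pool of 120 embryos and replicate 2 a pool of 88. The deposited files are peak lists on mm10. They comprise, for each replicate, a list thresholded on the irreproducible discovery rate (IDR), a pseudoreplicated list and an IDR-ranked list, and, for the series, a conservative list (IDR between the true replicates), an optimal list, a list of replicated peaks (overlapping between replicates, with no IDR threshold), a pooled pseudoreplicated list and 2 ranked lists. Peaks were called by the authors in each replicate and on pooled data. The aligner and the peak caller are not given in the sources used here. The signal value that the authors deposited for each peak is a ratio, the enrichment at the summit over the caller's local background, and was never below 1. The deposited -log10 p and -log10 q of each peak come from the same caller, and the -log10 q was not used. The deposited score of each peak is a scaled global IDR, whose minimum in the thresholded lists stands for a global IDR of 0.05, and the ranked lists give the -log10 of the local and global IDR as a score. In the 2 series-level ranked lists, 4 unnamed columns with values per replicate were not used. The provenance text files hold no measurement and were not used.

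Read counts were not analysed here, so the depth per sample is unknown, no interval that needs it is given, and the number of replicates (n = 2) limits the precision. Wilson 95% intervals on shares of peaks cover counting error over peaks only, and peaks with summits in the same region are not independent. A row of a list is a summit, and several summits can share 1 region, so the text counts summits as peaks and gives regions separately.

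Positions were compared with the GENCODE M21 annotation and the GRCm38.p6 sequence. A peak was TSS-proximal when its summit lay within 1000 bp of any annotated TSS and distal otherwise, and random positions on the same chromosomes gave the background. Overlap between replicates meant a shared stretch of at least 1 bp, and 100 random placements on the same chromosome gave the chance level. Summits of the replicates within 100 bp of each other were paired for the correlation, which is a description across peaks. A protein-coding gene had a promoter peak when a conservative summit lay within 1 kb of any of its TSSs. Its promoter enrichment was the highest of such peaks in each replicate's own thresholded list, as the mean and SD of both, and it is left out where either replicate's own list had no peak. Distal peaks of a gene were those within 100 kb of any of its TSSs.

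The 19 gene lists (305 genes) and the 27 consensus motifs were fixed before the files were opened. Promoter peaks of each list were compared with all other protein-coding genes by two-sided Fisher's exact test. Distal peak counts were compared by two-sided permutation test with 100000 random lists of equal size, matched on the decile of the number of protein-coding genes in the window. Motifs within 100 bp of a summit, on either strand, were compared with windows of the same width 1 kb to 5 kb away that overlap no deposited peak, matched on GC content in bins of 5 percentage points, by two-sided Fisher's exact test. Benjamini-Hochberg adjustment was made over the 19 lists or over the 27 motifs in both peak classes, with a threshold of 0.05. Genes are not replicates of the tissue, so these tests compare genes or peaks within it.

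Genes were named by a rule fixed before the files were opened. It takes in each list the 3 members with the highest promoter enrichment and the 3 with the most distal peaks, and every member where 5 or fewer have, or lack, a promoter peak. It also takes the 10 genes with the most distal peaks by nearest protein-coding TSS, the 10 strongest conservative peaks and the 3 strongest peaks of each replicate alone. A fuller set of values was computed than is printed.

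Alternatives fixed beforehand changed the TSS window (500 bp, 2.5 kb), the TSS set, the distal window (50 kb, 250 kb), the assignment of peaks to genes, the matching, the motif window (50 bp), the GC bins (2 points), the peak list, the enrichment threshold and the overlap rule (50% of both peaks, summits within 100 bp), and left out each replicate in turn by using the other's own list. Alternatives chosen after the data were seen were merged peaks for the overlap, 1 summit per region, a distal window around 1 TSS per gene, 1 gene per locus (members within 200 kb of each other counted once), random lists matched on the decile of promoter CpG content (observed over expected, 500 bp on each side of the gene's 5' end) and the direct comparison of motifs between distal and TSS-proximal peaks with all its settings. For the 9 regions of the strongest peaks and 200 random distal regions, matches to mitochondrial DNA (80% identity over 50% of the region) and further copies in the placed chromosomes (at least 2, at 90% identity over 80% of the region) were searched with BLAST+ 2.17.0.

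The tests were checked on simulated lists and sequences. Of the simulated changed lists 94% (promoters) and 99% (distal peaks) were recovered, with 3% and 2% of unchanged lists called, and all planted motifs were recovered with no other motif called. Changed lists had 95% or 10% of promoters open, against 60% of all genes, or 3-fold more or 12-fold fewer distal peaks. Motifs were planted in 2% of windows. Genes were simulated as independent, so these rates do not cover smaller changes or lists of neighbouring genes. Overlap, distance and motif functions were compared with direct enumeration. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9, with random seed 1.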

Results

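Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in the midbrain of B6NCrl mouse embryos at embryonic day 12.5. The samples form 1 group (E12.5 midbrain) with 2 biological replicates, a pool of 120 embryos (replicate 1) and a pool of 88 embryos (replicate 2), each of mixed sex. The deposited data are lists of peaks on the mm10 genome, called in each replicate and in the pooled data, and read counts were not analysed here, so the depth of each sample is unknown. Each peak carries an enrichment, the ratio of the signal at its summit to the caller's local background. Enrichments of single regions are given as the mean ± SD of the replicates' own lists (n = 2). With 1 group there is no contrast between conditions, and the comparisons are between gene groups, between promoters and distal regions, between peaks and their flanks, and between the replicates.

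The list called on pooled data and kept where the replicates agreed at an irreproducible discovery rate (IDR) of 0.05, named the conservative list here, held 68259 peaks in 24939 separate regions. These regions covered 26 Mb, 0.955% of the genome, with a median width of 1037 bp. Of the conservative peaks, 60.2% had a summit within 1 kb of an annotated transcription start site (TSS), with a Wilson 95% interval of 59.8 to 60.5%, against 6.11% of random positions. A further 17.9% lay in introns and 19.8% between genes. The share within 1 kb of a TSS was 72.5% in replicate 1 and 66.1% in replicate 2. It was 39.9% among peaks that overlapped between replicates without an IDR threshold.

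Genes of neural progenitors and of neurons had promoter peaks more often than other genes, at enrichments that were mostly below those of other promoters. All 18 neural progenitor genes had a conservative peak within 1 kb of a TSS. Among them, Id4, an inhibitor of bHLH factors (chromosome 13, 48261228 to 48266026), had the highest promoter enrichment, 12.1 ± 0.14. Vim, an intermediate filament of radial glia, had 7.96 ± 0.38 and Fabp7, a radial glia lipid-binding protein, 7.75 ± 0.87. Of the 17 pan-neuronal genes, 16 had a promoter peak. Syt1, the calcium sensor of synaptic vesicle release (chromosome 10, 108497650 to 109010982), reached 16.2 ± 0.03, Map2, a dendritic microtubule protein, 12.7 ± 1.11 and Elavl4, a neuronal RNA-binding protein, 11.5 ± 0.85. Nhlh2, a bHLH factor of early neurons, was the member without a conservative promoter peak, with 1 where no IDR threshold was set. Across all 21938 protein-coding genes, 12709 (57.9%) had such a peak, and the median promoter enrichment was 9.96, against 6.32 for the progenitor list and 6.13 for the pan-neuronal list (promoters measured in both replicates). By two-sided Fisher's exact test against the other protein-coding genes, with Benjamini-Hochberg adjustment over the 19 lists, the adjusted p was 0.000417 for neural progenitors and 0.00492 for pan-neuronal genes. Both calls ended when only the peaks in the upper part of the enrichment ranking were kept, and the progenitor call also ended without replicate 2 (14 of 18).

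Promoter peaks were also found at 17 of 18 housekeeping genes (exact adjusted p = 0.00318) and 14 of 15 cell cycle genes (exact adjusted p = 0.0124). Eef1a1, a translation elongation factor, had an enrichment of 14.7 ± 1.13, Sdha, a subunit of succinate dehydrogenase, 12.8 ± 0.77 and Rplp0, a ribosomal protein, 11.8 ± 0.13. Ubc, a polyubiquitin gene, was the exception, with 4 where no IDR threshold was set. In the cell cycle list, Ccnb1 (cyclin B1) had 14.7 ± 1.67, Ccna2 (cyclin A2) 14.7 ± 0.73 and Pcna, the sliding clamp of DNA replication, 14.6 ± 0.08. Aurkb, a mitotic kinase, lacked a peak in the conservative list and had 3 without the IDR threshold. Against random lists with the same promoter CpG content, a comparison added after the data were seen, neither list was called, with adjusted p values of 0.276 and 1.

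Midbrain lineage lists varied gene by gene and none was called at promoters. Of the 17 midbrain and midbrain-hindbrain boundary patterning genes, 12 had a promoter peak (exact adjusted p = 0.424). The share was 41.2% (7 of 17) without replicate 2 and 47.1% with 1 TSS per gene, both below that of other genes. It was 76.5% with a TSS window of 2.5 kb and 82.4% among overlapping peaks without an IDR threshold, and none of these was called. Pax5, a boundary transcription factor (chromosome 4, 44524757 to 44710487), had 15.2 ± 0.79, Spry2, a feedback inhibitor of FGF signalling, 8.73 ± 0.35 and En2, a midbrain-hindbrain homeobox factor (chromosome 5, 28165694 to 28172166), 7.73 ± 0.20. Pax2, Fgf8, Fgf17, Wnt1 and Lmx1b, which act at the boundary organiser, had none in the conservative list, although Pax2 and Lmx1b had 3 each without the IDR threshold. In the tectal and other midbrain glutamatergic list, 12 of 16 genes had a promoter peak (exact adjusted p = 0.306), among them the neuronal differentiation factors Ebf1 (11.5 ± 1.08) and Ebf2 (8.79 ± 0.27) and the tectal factor Pou4f1 (8.90 ± 0.65). Pax7, Lhx5, Barhl1 and Tfap2b lacked one in the conservative list, although replicate 2's own list had one for Pax7. That list was called higher with the optimal list (14 of 16) and with overlapping peaks under no IDR threshold (16 of 16).

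In the midbrain GABAergic list 8 of 12 genes had a promoter peak (exact adjusted p = 0.771). It was 6 of 12 without replicate 1, 5 of 12 without replicate 2, both below the share of other genes, and 11 of 12 among overlapping peaks without an IDR threshold, none of them called. Zfpm2, a GATA cofactor, had 9.82 ± 0.44, and the selector genes Tal2 and Tal1 had 5.28 ± 0.46 and 4.73 ± 1.07. Gad1, which encodes a GABA-synthesising enzyme, Slc32a1, the vesicular GABA transporter, and the factors Sox14 and Nkx2-2 had none in the conservative list, although Gad1, Slc32a1 and Nkx2-2 had 2, 1 and 4 promoter peaks without the IDR threshold. In the dopaminergic list 8 of 16 had one (exact adjusted p = 0.687). Nr4a2, needed for dopaminergic differentiation (chromosome 2, 57106830 to 57124003), had 9.50 ± 0.48, Msx1 5.95 ± 0.38 and the floor plate factor Foxa1 4.64 ± 0.49. The dopaminergic result depended on the peak list: 15 of 16 genes had a promoter peak among overlapping peaks without an IDR threshold, which was a call in the higher direction (exact adjusted p = 0.0251), and 4 of 16 without replicate 1, a call in the lower direction (exact adjusted p = 0.0365), or without replicate 2, with no call (exact adjusted p = 0.0682). Of the 10 oculomotor neuron genes, 5 had a promoter peak (exact adjusted p = 0.771). They were Nkx6-1 (11.8 ± 0.89), Isl1 (11.1 ± 0.34), Tbx20 (9.09 ± 0.45), Slc5a7 (5.78 ± 0.15) and Phox2a, with a peak in the conservative list and in replicate 2's own list. Phox2b, Chat, Slc18a3, Prph and Mnx1 had none in the conservative list. Without the IDR threshold Chat, Slc18a3 and Mnx1 had 2, 3 and 3, and the list reached 8 of 10, above the 64.8% of other genes and not called.

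Hox genes, which pattern the body axis behind the midbrain, had few accessible promoters: 2 of 39 had a peak (exact adjusted p = 5.76e-11). These were Hoxc13 (chromosome 15, 102921103 to 102928814; 7.54 ± 1.62) and Hoxd9, whose peaks were in neither replicate's own list. No Hoxa (n = 11) or Hoxb (n = 10) promoter had a peak, and 1 of 9 did in each of the Hoxc and Hoxd clusters. The list had 1 of 39 in each replicate's own list and 9 of 39 without the IDR threshold, all called lower. The Hox promoters stayed lower against random lists of equal CpG content, 5.13% against 79.4 ± 5.65% (SD over random lists), with a permutation adjusted p of 0.00038. Counting 1 gene per cluster left 4 genes, of which 1 had a peak, and no call (exact adjusted p = 0.461, Fisher's exact test).

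**Figure D1:**
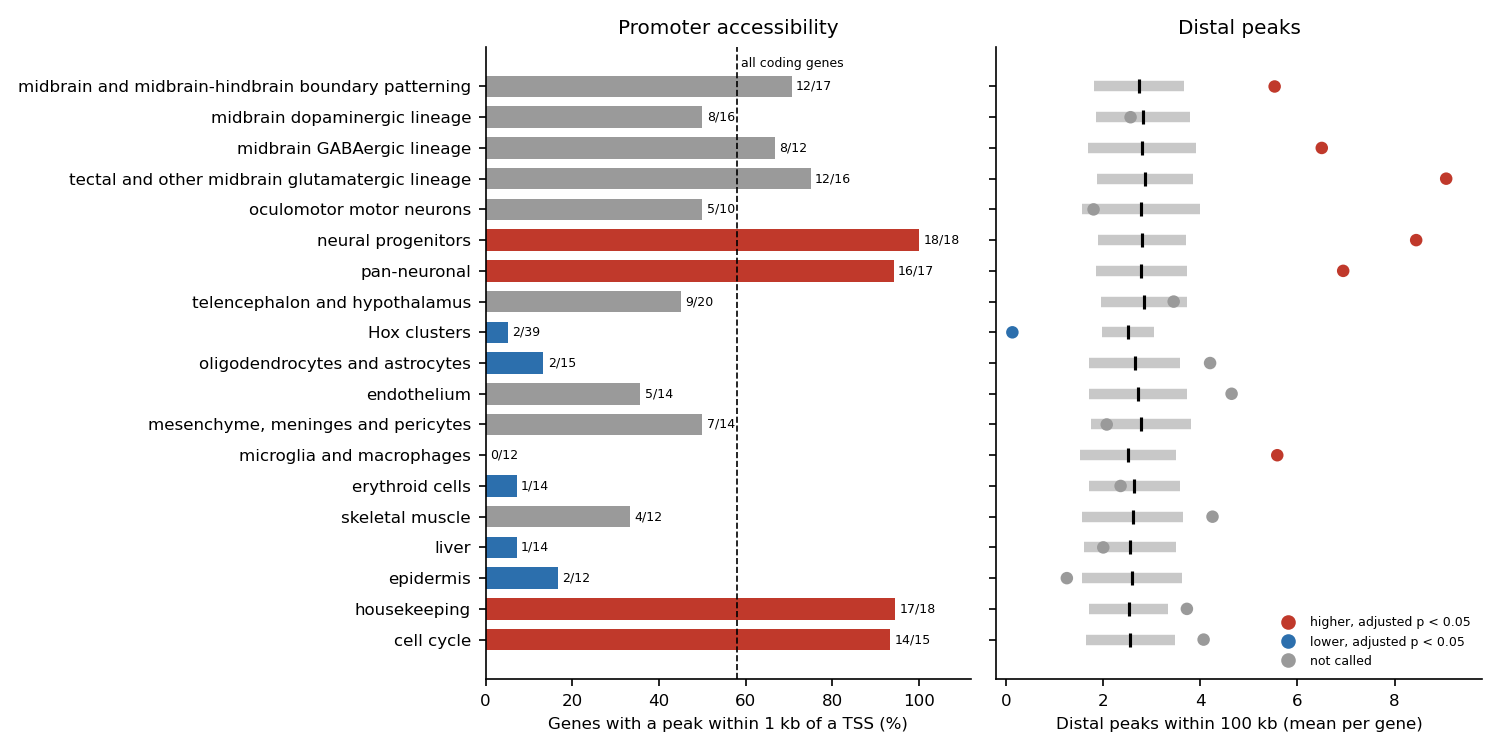
Promoter accessibility (bars, percent of each list's genes with a conservative peak within 1 kb of a TSS, with counts; dashed line, all protein-coding genes) and distal peaks (points, mean number of distal conservative peaks per gene within 100 kb; black ticks and grey bars, mean ± SD of random lists matched on gene density) for the 19 gene lists. Neural progenitor genes reached 18 of 18 promoters and Hox genes 2 of 39.

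Most non-neural lists, and the glial list, had few promoter peaks. None of the 12 microglia and macrophage genes had one (exact adjusted p = 0.000291). The erythroid list had 1 of 14, Tfrc, the transferrin receptor (12.5 ± 0.90), and the liver list 1 of 14, Apoh (10.4 ± 0.86), each with an adjusted p of 0.000417. In the epidermis list 2 of 12 had one, Perp (7.92 ± 0.99) and Krt1, whose peaks were in neither replicate's own list (exact adjusted p = 0.0122). In the oligodendrocyte and astrocyte list 2 of 15 had one, Olig2, a factor of motor neuron and oligodendrocyte precursors (8.35 ± 0.62), and Slc1a2, a glutamate transporter (4.08 ± 0.16; exact adjusted p = 0.00247). The last call ended with the optimal list (5 of 15) and without replicate 1 (4 of 15), and the epidermis call ended with a TSS window of 2.5 kb (4 of 12). Calls held without replicate 2 for the glial list (3 of 15), and without either replicate for the erythroid (2 of 14) and epidermis (1 of 12) lists. Lists of random genes with the same promoter CpG content had few peaks too, 18.9 ± 11.1% for the microglial list. Against these the microglia, erythroid, liver and epidermis lists were not called by permutation test (adjusted p of 0.276 or more), while the glial list was (permutation adjusted p = 0.00811). The microglial list could not have been called lower, since 0 of 12 is the floor and gave an unadjusted permutation p of 0.151. The erythroid and liver lists, each at 1 of 14, lay near that floor, so the missing calls decide little.

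Other lists were not called at promoters. The telencephalon and hypothalamus list had 9 of 20 promoters with a peak (exact adjusted p = 0.357), led by Sim1 (11.5 ± 2.06), Lhx8 (8.60 ± 0.37) and Dlx1 (8.41 ± 0.88), all homeobox or bHLH-PAS factors of forebrain regions. Against lists of equal CpG content that list was lower, 45% against 71.3 ± 8.13% (permutation adjusted p = 0.0218). The midbrain lists also lay below their CpG-matched lists, with no call (permutation adjusted p of 0.269 or more). They were oculomotor (50% against 75.1%), dopaminergic (50% against 67.5%), GABAergic (66.7% against 77.9%), glutamatergic (75% against 87.6%) and patterning genes (70.6% against 80.1%). CpG matching was run on the conservative list only. Among overlapping peaks without an IDR threshold 16 of 20 telencephalon and hypothalamus genes had a peak, above the share of other genes. That was not called by Fisher's exact test, which has no CpG matching, so whether the lower call holds there is not known. The endothelial list had 5 of 14 (exact adjusted p = 0.186): Ets1 (13.1 ± 1.03), Erg (9.36 ± 2.97), Kdr, Egfl7 and Sox17. The mesenchyme list had 7 of 14 (exact adjusted p = 0.687), led by Pdgfra (7.57 ± 0.82), Tbx18 (7.16 ± 0.29) and Foxc1 (7.15 ± 0.41), with 8 of 14 without replicate 1, 4 of 14 without replicate 2 and 10 of 14 without the IDR threshold, none of them called. The skeletal muscle list had 4 of 12 (exact adjusted p = 0.222): Actn3 (11.4 ± 2.67), Mylpf (9.70 ± 0.59), Myf6 and Ckm. The endothelial and muscle lists were called lower with a TSS window of 500 bp (3 of 14 and 1 of 12) and without replicate 1 (3 of 14 and 2 of 12), while 8 of 14 endothelial promoters had a peak without the IDR threshold.

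Distal peaks, with summits over 1 kb from every TSS, were more numerous than in random lists around 6 of the 19 lists and fewer around the Hox list. Several summits can share a region, and with 1 summit counted per region, an alternative chosen after the data were seen, the same 6 lists were called higher, at 2.22 to 3.17 times the random mean, and the Hox list lower. Glutamatergic lineage genes had a mean of 9.06 distal peaks within 100 kb, 3.17 times the 2.86 ± 0.99 (SD) of random lists matched on gene density, and neural progenitor genes had 8.44, which was 3.02 times. Neurog2, a proneural factor (chromosome 3, 127633135 to 127635631), had 20 distal peaks in 7 regions. The own lists of replicate 1 and replicate 2 held 17 and 25 there, and counts from these lists are given in the same order in parentheses below. Its strongest lay 29256 bp from the TSS (summit at 127662391) with an enrichment of 6.03 ± 0.36. Meis2 had 17 (6 and 10) and Ebf1 14 (2 and 9). In the progenitor list, Sox9, a factor of neural stem cells and glia, had 20 (11 and 16) in 6 regions, with the strongest at 112870297 on chromosome 11 (12.5 ± 0.83), and the Notch effector Hes5 (11 and 16) and the receptor Notch1 (8 and 13) had 15 each. By two-sided permutation test the adjusted p was 0.000127 for both lists, at the smallest raw p that the 100000 random lists allow, 2e-05.

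Pan-neuronal genes had 2.49 times the distal peaks of matched random lists (permutation adjusted p = 0.00295). Nhlh2, which lacked a promoter peak, had 15 (1 and 13), and 26 among overlapping peaks without an IDR threshold. Myt1l, a neuronal zinc finger factor, had 14 (6 and 9) and Nhlh1 12 (7 and 12). The GABAergic list had 2.32 times as many (permutation adjusted p = 0.0306). In it, Ascl1, a proneural factor (chromosome 10, 87490819 to 87493660), had 16 (12 and 19) in 6 regions, the strongest 45809 bp from its TSS (13.4 ± 1.57), Gata2 had 13 (8 and 10) and Tal1 11 (8 and 9). The patterning list had 2.02 times as many (permutation adjusted p = 0.0353). Lmx1b, with no promoter peak, had 13 (5 and 9), the strongest inside the gene (6.80 ± 0.75), and the neighbours En2 and Cnpy1 shared 10 (3 and 8). Wnt1, also without a promoter peak, had 8 (4 and 4), the strongest 8305 bp from its TSS (10.8 ± 0.26). The microglia and macrophage list had 2.23 times as many (permutation adjusted p = 0.032), with 12 near Ptprc (0 and 2), most of them in neither replicate's own list, and 9 near the adjacent C1qa and C1qb (6 and 4). With 1 gene per locus, an alternative chosen after the data were seen, the microglial and patterning lists were not called (adjusted p of 0.18 and 0.101). The microglial call also ended without replicate 1 (1.53 times) and without replicate 2 (1.91 times), and the patterning (2.25 times) and GABAergic (2.48 times) calls ended without replicate 2. By nearest TSS none of the 3 lists was called.

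The Hox list had fewer distal peaks than any other, a mean of 0.128 per gene, 0.051 times the random mean (permutation adjusted p = 0.000127). Hoxb1 had 4 and Hoxc4 had 1, with 0 near both genes in each replicate's own list. Summits within 1 kb of any annotated TSS, non-coding ones included, were not distal, while matching used protein-coding genes only. In the HoxD region some conservative peaks, with enrichments up to 6.08, thus counted neither as distal nor at the promoter of a listed Hox gene. How much of the deficit comes from this rule was not tested. With 1 gene per cluster there was no call (n = 4, permutation adjusted p = 0.202), nor by nearest TSS (permutation adjusted p = 0.127). In both the ratio was 0, the lowest possible, so the list could not have been called lower and these outcomes decide nothing. At 250 kb the list stayed lower, but at 0.604 times the random mean, and it was at 0.468 times without the IDR threshold. Not called were the dopaminergic list (0.909 times; permutation adjusted p = 0.886), in which Ddc, the enzyme that makes dopamine from L-DOPA, had 13 (4 and 7) and Foxa2 10 (2 and 7), and the oculomotor list (0.649 times; permutation adjusted p = 0.602), in which Prph had 9 (5 and 6). The ratio was 1.22 for the telencephalon and hypothalamus list, where Rax had 10 (2 and 7) and Foxg1 9 (3 and 5) (permutation adjusted p = 0.602), 1.59 for the glial list (0.249), 1.71 for endothelium (0.207), 0.745 for mesenchyme (0.646) and 0.892 for erythroid genes (0.886). It was 1.63 for skeletal muscle (permutation adjusted p = 0.252), 0.782 for liver (0.699), 0.482 for epidermis (0.253), 1.48 for housekeeping (0.253) and 1.59 for cell cycle genes (0.249).

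**Figure D2:**
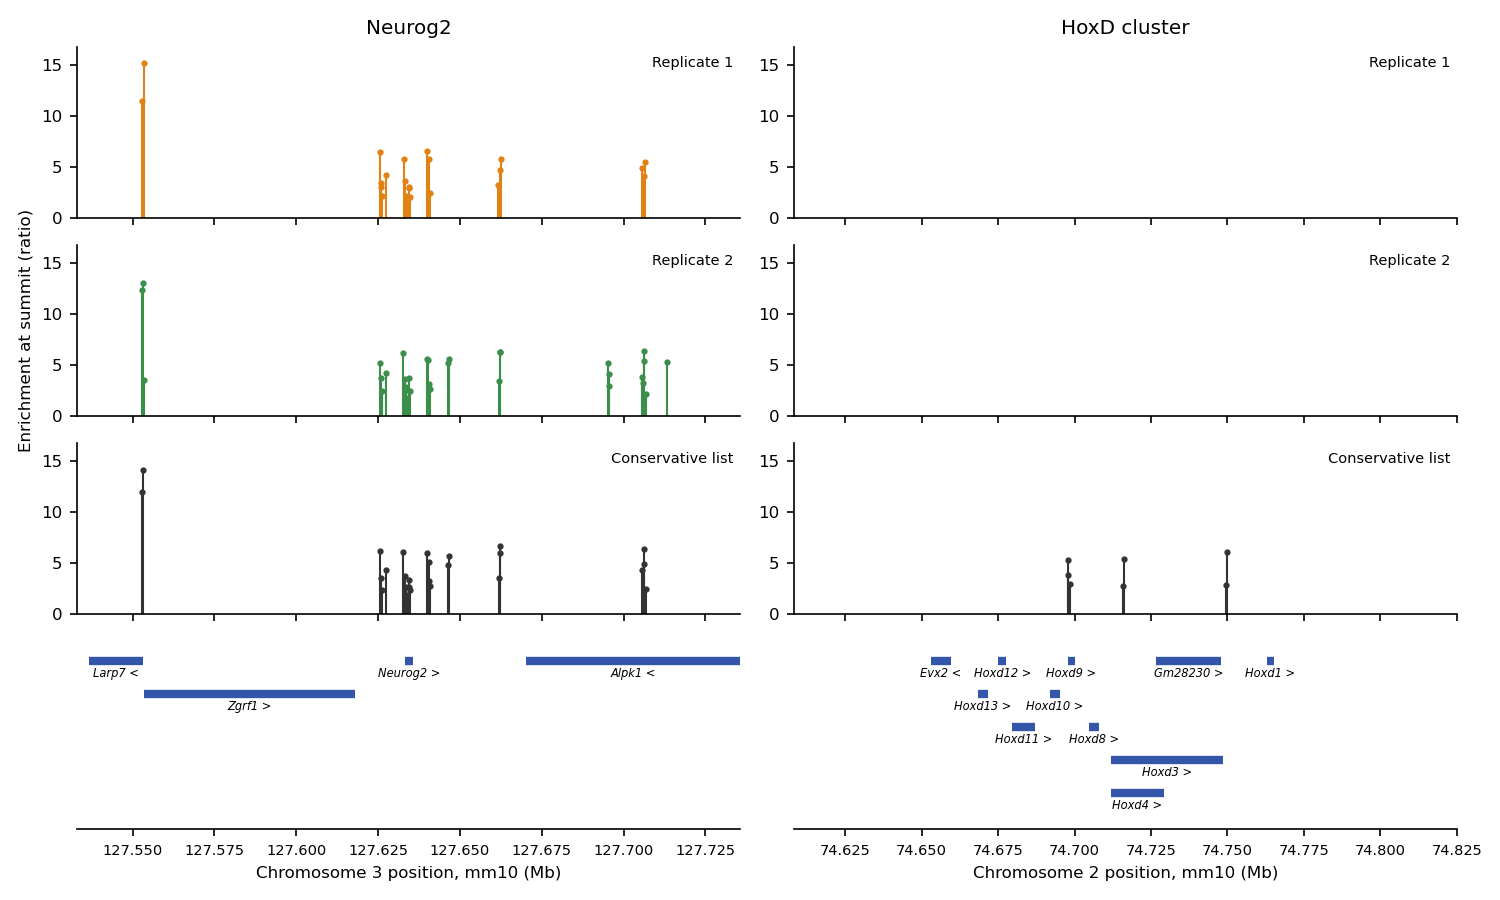
Peak summits in 2 regions of the mm10 genome (horizontal axis, position in Mb; vertical axis, enrichment at the summit as a ratio) in each replicate's list and in the conservative list, with protein-coding genes below and their strand as > or <. Around Neurog2 both replicates hold peaks on either side of the gene, while in the HoxD region neither replicate's own list has a peak and the conservative list has 3 regions.

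When each distal peak was given to the nearest protein-coding TSS only, Zfp608 had the most, 52 (18 and 40). Rapgef5 had 51 (31 and 44), Celf4, an RNA-binding protein of neurons, 50 (29 and 37) and Tenm3, a teneurin adhesion protein, 45 (14 and 22). Adgrl2 had 43 (10 and 33), Sox9 42 (20 and 33), the Notch coactivator Maml3 41 (17 and 30) and the presynaptic neurexin Nrxn3 41 (23 and 27). The nuclear receptor Nr2f1 (27 and 30) and the teneurin Tenm4 (19 and 30) had 37 each. The strongest distal peak near Maml3 lay inside the gene (chromosome 3, summit at 51701647) with 12.2 ± 0.28, and the strongest near Nrxn3 also lay inside it (12.3 ± 0.34). Over all protein-coding genes the median within 100 kb was 1 distal peak and 44.2% had none.

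Sequence motifs at distal summits included those bound by CTCF, RFX, POU, homeobox, SOX and proneural bHLH factors. The CTCF consensus lay within 100 bp of 2.67% of distal summits, against 0.111% of GC-matched flanking windows, an odds ratio of 24.6 (exact adjusted p = 2.86e-161). The short RFX site was at 2.09% against 0.545% (odds ratio 3.88) and the POU octamer at 2.81% against 0.935% (3.06). The homeobox core TAATTA was at 6.50% against 3.01% (2.24), the SOX site at 12.2% against 6.66% (1.95) and the proneural E-box CAGCTG at 19% against 12.3% (1.67). Smaller odds ratios were found for the OTX/PITX site (1.30), the TCF/LEF site (1.22), the E-box CATCTG (1.18) and the FOX site (1.18). MEIS/PBX (3.92), NRF1 (3.75), the SP/KLF GC box (2.13), the NFY site (1.95) and the rare RFX palindrome (31.0, from 31 peaks and 1 flank) were also higher. The GATA site (0.836) and the E-box CACCTG (0.668) were lower than in flanks. AP-1, TEAD, ETS, YY1, PU.1, MEF2, REST, NFI, HNF1 and p53 sites were not called. These are two-sided Fisher's exact tests on 25123 matched distal peaks, adjusted over 27 motifs in both classes of peak. Summits that share a region are not independent, so the p values and intervals of all motif tests cover counting error over summits only. The TAATTA enrichment rests on GC matching, since distal summits averaged 51.3% GC and flanks 43.9%, and without matching its odds ratio was 0.968; that of FOX was 0.847. The FOX call ended in windows of 50 bp and above the median enrichment, the TCF/LEF call without GC matching and the GATA call in windows of 50 bp, without either replicate and without the IDR threshold. The NRF1 call ended in windows of 50 bp, in GC bins of 2 points, without either replicate and with 1 summit per region.

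Promoter summits shared most of their enriched motifs with distal summits, at other odds ratios, while YY1, ETS and NFI were called higher only at promoters. For NFI the distal odds ratio was 2.20 (11 peaks and 5 flanks). Distal and proximal summits set against each other did not differ in NFI (odds ratio 0.667, exact adjusted p = 0.647). YY1 (odds ratio 54.1, from 54 peaks and 1 flank), NRF1 (14.7), ETS (9.17), NFY (4.57) and the SP/KLF GC box (2.64) were higher than in GC-matched flanks, with adjusted p from 8.77e-83 for ETS to 1.01e-14 for YY1. NFI (7, from 14 peaks and 2 flanks), MEIS/PBX (5.31), CTCF (2.56) and POU (2.52) were higher too. The short RFX site (1.90), TAATTA (1.67), FOX (1.41), SOX (1.16) and the RFX palindrome (10 peaks and 0 flanks) were also higher. The E-boxes CAGCTG (0.796), CATCTG (0.742) and CACCTG (0.574), AP-1 (0.725) and OTX/PITX (0.896) were lower. Matching kept 19261 of 41058 TSS-proximal peaks, since these averaged 62.4% GC against 44.4% in flanks. Without matching the direction turned for SOX, CAGCTG, TAATTA, POU and FOX. The FOX call ended without either replicate (1.08 without replicate 2 and 1.09 without replicate 1), as did that of OTX/PITX, which ended under 4 other alternatives too. The NFI call ended without replicate 2, in windows of 50 bp and in GC bins of 2 points, that of the RFX palindrome without replicate 2 and in windows of 50 bp, that of AP-1 in windows of 50 bp and that of CAGCTG with 1 summit per region.

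Set against each other at equal GC content, a comparison added after the data were seen, distal and TSS-proximal summits differed in 17 of the 27 motifs. CTCF sites were at 2.77% of distal and 0.627% of proximal summits (odds ratio 4.52, exact adjusted p = 1.65e-59), CAGCTG at 21.3% and 12% (1.97, exact adjusted p = 6.58e-123) and SOX sites at 11.6% and 6.37% (1.94, exact adjusted p = 9.37e-69). CATCTG (1.61), the short RFX site (2.08), POU (1.79) and TAATTA (1.52) were also more frequent in distal summits, although the POU call ended above the median enrichment (1.23) and with 1 summit per region (1.23). AP-1 (1.30), TCF/LEF (1.23), OTX/PITX (1.12), TEAD (1.12) and the RFX palindrome (4.6, from 23 distal summits) were called higher too, and AP-1 and TEAD had not been called in distal peaks against flanks. The TEAD and RFX palindrome calls each ended under 4 alternatives, and the TCF/LEF call with 1 summit per region. ETS (0.160), YY1 (0.127), NRF1 (0.342), NFY (0.546) and SP/KLF (0.793) sites were less frequent there. The test used 18177 summits of each class.

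**Figure D3:**
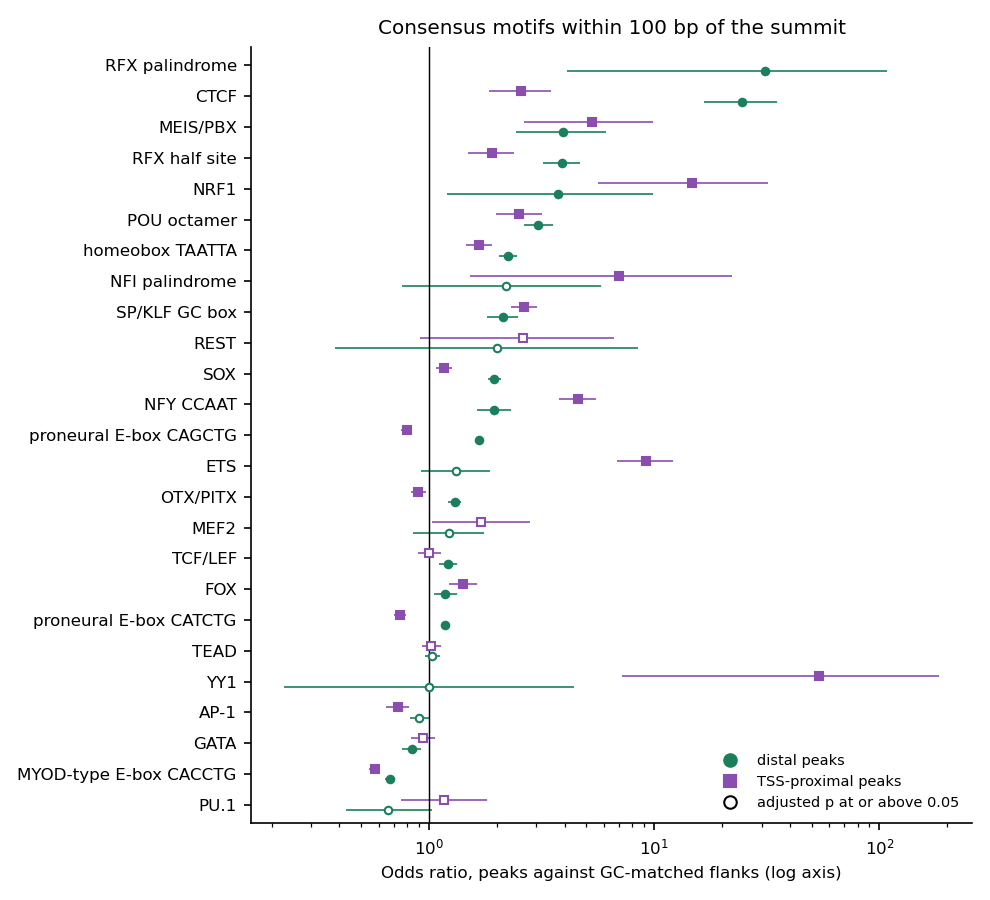
Odds ratio (log axis) of each consensus motif within 100 bp of peak summits against GC-matched flanking windows, for distal (green circles) and TSS-proximal (purple squares) peaks, with 95% intervals; open symbols were not called and motifs with no finite ratio are left out. CTCF stands at 24.6 in distal peaks and 2.56 in proximal peaks, and ETS at 1.32 and 9.17.

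The 10 strongest conservative peaks lay in 9 regions, and none was at the promoter of a protein-coding gene. The highest was on chromosome X between genes, 35531 bp from the TSS of Pak3 (143482936 to 143483180), with an enrichment of 54.8 ± 1.27. The next was on chromosome 2 near Abcb11 (69355470 to 69355735; 50.2 ± 1.05). Then came regions on chromosome 10 near Gm5426 (41.0 ± 1.70), chromosome 2 near Frmd4a (40 ± 4.20) and chromosome 5, with G6pd2 as the nearest protein-coding gene (37.0 ± 2.31). A region on chromosome 12 (97061367 to 97061856), nearest to Galc but over 1 Mb away, held 2 of the 10 summits (29.0 ± 0.80 and 26.4 ± 0.84). The others were on chromosome 4, 606 bp from the TSS of the pseudogene Gm11407 and 831186 bp from that of Tyrp1, the nearest protein-coding gene (26.2 ± 1.89), on chromosome X in an intron of Cldn34d (25.4 ± 2.73) and on chromosome 8, 190 bp from the TSS of the pseudogene Gm10060 and 55360 bp from that of 4930467E23Rik (24.8 ± 0.17). Of the 9 regions, 4 matched the mouse mitochondrial genome over most of their length at 80% identity or more, and the Abcb11 region matched it over 48.5%. None of 200 random distal regions matched (Fisher's exact p = 1.63e-06, two-sided).

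The replicates shared most of their peaks. Replicate 1 had 45416 peaks over 17.3 Mb and replicate 2 had 55116 over 21 Mb, a ratio of 1.21. Of replicate 1's peaks 94.3% overlapped one of replicate 2's (Wilson 95% interval 94.1 to 94.6%), and of replicate 2's 79.9% overlapped one of replicate 1's (79.5 to 80.2%). Random placement on the same chromosome gave 1.74% and 1.42%. Across 33944 pairs of summits the enrichments had a Spearman correlation of 0.944 and a Pearson correlation of 0.941 on the log2 scale. These are across peaks, which are not independent replicates. The median log2 ratio of enrichment, replicate 2 over replicate 1, was -0.03, and 37 pairs differed by over 2-fold. Promoters of 11364 protein-coding genes had a peak in replicate 1 and 12118 in replicate 2, with 11136 in both.

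**Figure D4:**
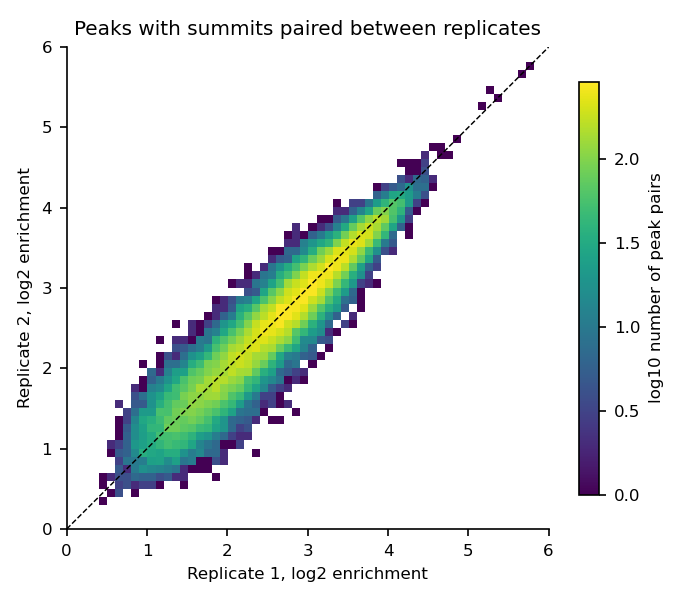
Log2 enrichment of 33944 peaks with paired summits in replicate 1 (horizontal axis) and replicate 2 (vertical axis); colour gives the log10 number of pairs and the dashed line marks equal values. The pairs lie along the line, with a median log2 ratio of -0.03.

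Peaks found in 1 replicate only were mostly distal and weaker. Replicate 1 had 2567 such peaks (5.65%) with a median enrichment of 5, against 5.47 for its shared peaks, and 30% lay within 1 kb of a TSS, against 75.1% of shared ones. Replicate 2 had 11092 (20.1%), with a median of 4.37 against 5.19 and 33.5% against 74.3% within 1 kb of a TSS. The 3 strongest in replicate 1 were between genes on chromosome 8 (4868847 to 4869363; 12.4), between genes on chromosome 18 (63555205 to 63556063; 11.8) and at the promoter of Uty on chromosome Y (11.6). In replicate 2 they were at the promoter of Cyb5r1 on chromosome 1 (13.8), between genes on the same chromosome (102627905 to 102628394; 12.6) and in an intron of Tgfbrap1 (12.2). All 6 were in the other replicate's longer list without an IDR threshold, as were 95.9% of replicate 1's and 93.5% of replicate 2's single-replicate peaks. No test between replicates was run, as each is 1 sample.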

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

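Of the tests in this part, those of mitochondrial DNA and of further copies over all 9 strongest regions, and that of cell mix, were set before the results were seen, and the others were chosen afterwards.

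Peaks in data that the comparisons did not use were found by setting the ranked lists against the thresholded ones. In replicate 1, 203 of 45619 ranked peaks at the IDR threshold were left out of the thresholded list, and in replicate 2, 239 of 55355. Of these, 61 and 75 were on unplaced sequence. The strongest by -log10 p (4326 and 4962) were on chromosome 1 at 24611587 to 24616165 and 24611579 to 24616160, and both matched mitochondrial DNA over 100% of their length at 99.956% identity. They met the rule for a signal in data outside the main measurement.

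The strongest conservative peaks lay away from protein-coding promoters. Of their 9 regions, 4 matched mitochondrial DNA over at least 50% of their length, those whose nearest protein-coding genes are Gm5426 (86.7%), G6pd2 (89.1%), Galc (74.5%) and Tyrp1 (99.7%), against 0 of 200 random distal regions. The bound set beforehand was 5 of 9, so whether nuclear copies of mitochondrial DNA account for the whole set is left open by that test, with the Abcb11 region just short at 48.5%. For the 5 regions with any match it stays open, since reads were not analysed here. The other 4 regions (Pak3, Frmd4a, 4930467E23Rik and Cldn34d) had no match, which argues against a close mitochondrial copy there. The search could miss short or more diverged copies, so those are not excluded. Of the 9 regions, 1 had 2 or more further copies of its sequence on the placed chromosomes (4930467E23Rik, 6 copies). G6pd2 and Tyrp1 had 1 each, so further copies stay open as an explanation for these 3. Copies of that kind are argued against for the other 6, which had none. The search left out unplaced sequence, mitochondrial DNA and copies over less than 80% of the region, so these are not excluded. No biological explanation was tested.

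Replicate 2 had more peaks, 55116 against 45416. At shared peaks the -log10 p was 1.29 times higher in replicate 2 while the enrichment ratio was 0.981, which is consistent with more statistical power in replicate 2. Its source was not tested, since read depth was not analysed here. A different mix of cell types stays open. Among the 11 lists with 3 or more promoters measured in both replicates, the largest departure of the median log2 ratio from that of all genes was 0.19, for mesenchyme (SD 0.12, n = 4). That is below the 0.25 set beforehand, but by less than its SD, a margin applied after the value was seen. The test also leaves out promoters with a peak in 1 replicate only: mesenchyme had 4 of 14 promoters in replicate 1 and 8 in replicate 2, and patterning genes 7 and 12 of 17, against 11364 and 12118 of all genes. The pools differ in their number of embryos (120 and 88) and may differ in ways the labels do not describe. No biological explanation was tested.

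Promoters of several non-neural lists lacked peaks. The microglia, erythroid, liver and epidermis lists have promoters of low CpG content, and genes of the lowest CpG decile had a promoter peak in 4.88% of cases, against 96.3% in the highest. All 7 non-neural lists together, with endothelium, mesenchyme and muscle, had a peak at 21.7% of 92 promoters, against 58.1% of other genes and 33.5 ± 3.96% of CpG-matched random lists (permutation p = 0.00298). This pool of every non-neural list was formed after the lists had been tested singly and the 4 lowest together, a set chosen by its result. Low CpG content is thus argued against as the whole cause for the 7 lists together, although none of them alone was called against matched lists. Matching used CpG content at 1 TSS per gene, while a peak counted at any TSS of the gene. Neighbouring genes were counted separately, so the permutation p is limited by both. For the Hox list low CpG content is argued against as the whole cause by a permutation adjusted p of 0.00038. A loss of weak promoters to the IDR threshold is argued against only as the whole cause. Without the threshold the Hox share rose from 5.13% to 23.1%, and that of other genes from 58.0% to 64.9%. Both tests counted genes of a cluster separately, and with 1 gene per cluster Fisher's exact test gave no call. A single closed cluster counted many times is argued against as well, since no cluster exceeded 11.1%, and a repressed state of Hox promoters in midbrain stays a hypothesis, found and examined in the same data.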

How the results depend on the processing

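Settings with 1 gene per locus, 1 summit per region, merged peaks in the overlap, CpG-matched lists, a distal window around 1 TSS per gene, and all settings of the direct motif comparison were chosen after the data were seen. Of 2059 alternative values, 1508 kept their side of the threshold or moved little, 64 lost a call, 34 gained one, 434 moved and 19 turned. Of the 1508, 72 changed direction with no call on either side. Read depth is unknown, so what it limits could not be set apart from the threshold. Where no cause is stated below, the cause was not tested.

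Peak numbers moved with the list and with merging. Pseudoreplicated lists held 87700 and 103191 peaks (ratio 1.18), merging left 17101 and 20995, and 24939 of the conservative list, and a global IDR of 0.01 gave a ratio of 1.27. The shared share of replicate 1 and replicate 2 was 92.6% and 78.0% with 50% of both peaks, 75.2% and 61.9% with summits within 100 bp, 89.2% and 78.6% with pseudoreplicated peaks, 95.2% and 84.3% with peaks above the median enrichment, and 92.3% and 74.8% with merged peaks. The Spearman correlation was 0.954 for TSS-proximal peaks, 0.894 for distal peaks, 0.942 with -log10 p and 0.875 with all ranked peaks. The TSS-proximal share was 50.7% at 500 bp, 64.9% at 2.5 kb, 56.1% with protein-coding TSSs, 58.1% with the optimal list, 39.9% with replicated peaks, 63.7% above the median enrichment, 54.3% with 1 summit per region, and 66.1 to 72.5% without either replicate.

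For peaks of replicate 1 only, pseudoreplicated lists gave 9451, with 12.5% TSS-proximal and a median enrichment of 3.35, and merging gave 1325, with 26% and 6.29. For replicate 2 these were 22055, 12.6% and 3.07, and 5288, 29.0% and 5.65. With 50% of both peaks the TSS-proximal share was 35.1% and 34.9%, and the share in the other replicate's pseudoreplicated list 96.9% and 94.0%, against 93.7% and 90.8% with merged peaks. That share has no value for the pseudoreplicated lists, which it uses.

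Promoter lists: 2 lists were called higher above the median enrichment, where neural progenitors fell to 77.8% and pan-neuronal genes to 76.5%. Matched on CpG content, 2 were higher and 3 lower, among them telencephalon (45%). The call ended for microglia (0%), erythroid (7.14%), liver (7.14%), epidermis (16.7%), housekeeping (94.4%) and cell cycle genes (93.3%). The matched lists lay at 18.9 to 29.1% for microglia, erythroid, liver and epidermis, and at 80.4% and 90.8% for housekeeping and cell cycle genes. That left little room for a call. With 1 gene per locus the Hox share was 25% of 4 genes, too few for a call. Replicated peaks turned the dopaminergic list to 93.75%, a call in the higher direction, and gave 100% for glutamatergic genes (87.5% with the optimal list). The glial list rose to 33.3% with the optimal list, and epidermis to 33.3% at 2.5 kb. At 500 bp endothelium (21.4%) and muscle (8.33%) were called lower, as was endothelium with 1 TSS per gene (14.3%). Without either replicate the range was 25 to 25% for dopaminergic genes, 77.8 to 83.3% for neural progenitors, 20 to 26.7% for the glial list, 21.4 to 21.4% for endothelium and 16.7 to 25% for muscle.

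Distal lists: nearest-TSS counts called 3 lists higher and 0 lower, and 3 to 5 were higher without either replicate. With 1 gene per locus 0 were lower. The patterning ratio lost its call at 250 kb (1.57), by nearest TSS (2.12), with 1 gene per locus (1.92) and without replicate 2 (range without either, 2.19 to 2.25). The GABAergic ratio lost it at 250 kb (1.60), by nearest TSS (2.19), above the median enrichment (1.96) and without replicate 2 (range without either, 2.48 to 2.65). The microglial ratio lost it by nearest TSS (3.65), without density matching (2.13), with the optimal list (1.85), above the median enrichment (1.86), with 1 gene per locus (1.95) and in the range 1.53 to 1.91 without either replicate. The Hox ratio was 0 by nearest TSS and with 1 gene per locus, the lowest possible value, at which no lower call could be made. Telencephalon gained a call at 250 kb (1.63) and the glial list with replicated peaks (1.93).

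Motifs: the number lower in distal peaks was 1 with 50 bp windows, 4 with unmatched flanks, 1 with replicated peaks and 1 to 2 without either replicate; in proximal peaks it was 12 with unmatched flanks and 3 with 1 summit per region. Unmatched flanks turned odds ratios in distal peaks for YY1 (5.60), TAATTA (0.968), MEF2 (0.746) and FOX (0.847). In proximal peaks they turned SOX (0.749), CAGCTG (1.44), TAATTA (0.271), POU (0.720), TCF/LEF (0.447), TEAD (0.755), MEF2 (0.511) and FOX (0.503); summits are richer in GC than flanks, by 51.3 against 43.9% (distal) and 62.4 against 44.4% (proximal). OTX/PITX turned with 1 summit per region (1.03), and NFI (0.800) and TEAD (0.853) with 50 bp windows. In the direct comparison CACCTG turned with replicated peaks (1.16), above the median enrichment (1.18) and with 1 summit per region (1.47).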

Other observations

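Chromosome X had fewer accessible regions per Mb than any autosome. It held 4.40 conservative regions per Mb, against 7.42 (chromosome 14) to 12.5 (chromosome 11) on the autosomes, and 1.54 distal regions per Mb against 3.52 to 5.25. Its density of protein-coding genes, 5.54 per Mb, lay between those of chromosome 12 (5.35) and chromosome 18 (5.66), which held 8.87 and 9.16 regions per Mb. Both pools were of mixed sex, and the copy number of chromosome X, lower in male embryos, was not accounted for. Chromosome Y held 13 regions.

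Several named genes of the telencephalon and hypothalamus, glial, mesenchyme and epidermis lists had distal peaks within 100 kb and no promoter peak in the conservative list. The rule names each list's members with the most distal peaks, and of all protein-coding genes only 44.2% had none within 100 kb. The strongest distal peak within 100 kb of Mog, a myelin protein gene, had an enrichment of 13.6 ± 1.13 (SD, n = 2) and lay 5364 bp from its TSS. For Pomc, the precursor of melanocortins, it was 11.1 ± 0.03 at 5050 bp, inside the gene, and for Lor, an epidermal envelope protein, 6.64 ± 0.59. Aldh1l1, an astrocyte enzyme, had 14 distal peaks within 100 kb and Col1a1, a collagen chain, 11, although replicate 2's own list had a promoter peak for both. Krt14, a basal keratin, had 4 distal peaks, none of them in a replicate's own list.

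The replicated peaks, which have no IDR threshold, numbered 126232 in 60346 regions covering 43.0 Mb, against 26 Mb for the conservative list. The median enrichment was 3.33 there and 4.54 in the conservative list. Of the peaks found in 1 replicate only, 97 in replicate 1 and 711 in replicate 2 were absent even from the other replicate's ranked list, with median enrichments of 5.05 and 4.74.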
